A study of Mus musculus with 24 samples.

How the data were processed

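Total RNA was sequenced from C127 cells, a mouse mammary adenocarcinoma line (written C127l in the labels). Per the labels, the cells lacked their own glucocorticoid receptor and carried GFP-tagged mouse receptor, either wild type (GFP-mGRwt, here wt) or a form called GFP-mGRtetra (here tetra), which the labels do not describe further. Cells of each line were given vehicle, 100 nM corticosterone (Cort) for 2 h, 100 µM TCA for 2 h, or TCA plus Cort. TCA is not spelled out in the labels, and in a series on bile acids its usual reading is taurocholic acid. The 24 samples form 8 groups of 3. Per the labels' protocols, cells were kept in charcoal-stripped serum for 24 h, ribosomal RNA was removed with Ribo-Zero Plus, and the libraries were stranded (TruSeq).

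The authors deposited 6 tables, each with 6 libraries and a comparison of a treated group with its control: TCA with vehicle, Cort with vehicle and TCA plus Cort with TCA, in wt and in tetra. Per the submitters' processing notes, reads were trimmed with cutadapt (version not given), aligned to mm10 with STAR 2.7.0f and counted with HOMER 4.10.4. Per the file headers, exon reads were summed over RefSeq transcripts, condensed to a single entry per gene, and turned into variance-stabilised values on a log2-like scale separately for each table. The headers state no strand setting, so reads of overlapping genes on opposite strands may be mixed in the counts. The deposited log2 fold change and the deposited p-value and adjusted p-value are the authors' own and were used only where the text names the authors' deposited table. The table of TCA in tetra held 26188 genes and a newer set of symbols, and the other 5 held 25124.

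The deposited scale was inverted for each table to recover read counts. In every library 100% of the recovered values below 1000 lay within 0.01 of a whole number. The deposited value of a count of 0 ranged from 6.32 to 8.61 between tables and was the same in all libraries of a table, so deposited values were compared across tables only as an alternative for the differences. Recovered exon reads per library ranged from 22.02 M to 30.6 M, of 31.1 M to 42.3 M tags named in the headers. A floor of 3 counts equals 0.0981 to 0.136 CPM of exon reads, and such floors cover counting error only, since the reads carry no molecular identifiers. Libraries of the same group differed by more than counting error (chi-square per gene between 2.38 and 33.8 over 24 pairs), with a Pearson r across genes of at least 0.991. All 24 library columns were matched to a sample. Libraries that appear in more than 1 table were counted once in the plot of principal components.

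Values in the text are normalised read counts, the recovered counts divided by the size factor that each table's deposited scale implies, as mean ± SD with n = 3 per group. Fold changes are ratios of those means within a table. TCA plus Cort against Cort, the principal components, the distances between group means and the test of a mixture join libraries of different tables. For these the recovered counts were scaled anew, with size factors from median ratios over the libraries joined. TCA plus Cort against Cort was tested on log2 of the resulting count plus 1. Each comparison was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on the deposited values of the 6 libraries of its table, over genes with a mean normalised count of at least 10. Adjusted p-values are Benjamini-Hochberg values from limma over the genes tested, and a gene counts as called below 0.05. For a difference between comparisons, limma was fitted to log2 of the normalised count plus 1 over the 12 libraries, because the deposited scale differs between tables; this departs from the design, which named the deposited values for all tests. Symbols absent from either table could not enter a difference. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

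The samples' groups, the tests, the filter, 20 gene lists and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, up to 12 rises and 12 falls with the largest change among called genes with a mean of at least 50 and groups that do not overlap (chance gives 10% for 3 against 3). It names 8 and 8 per difference, up to 4 members with the smallest adjusted p per list described, and a panel of 10 genes: Nr3c1, Fkbp5, Tsc22d3, Per1, Sgk1, Dusp1, Zbtb16, Klf9, Mt2 and Lcn2. A gene named outside the rule is marked in the text, and 1 gene that the rule names is not reported here. The lists cover glucocorticoid-induced, inflammatory, immediate early, bile acid receptor, cholesterol synthesis, unfolded protein response, heat shock, NRF2 oxidative stress, circadian clock, steroid receptor machinery, cell cycle, p53 and YAP target genes, markers of epithelial, mesenchymal, immune and endothelial cells, ribosomal protein genes, replication histone genes and small nuclear and nucleolar RNAs. Lists with at least 5 tested members were tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists of the comparison, and again with an estimated correlation. The marker lists stand for other cells a culture could hold, and the ribosomal protein, histone and small RNA lists for library composition. List counts are given over all genes tested and adjusted over the list alone. Genes with near-identical copies or overlapping neighbours are given as uncertain.

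The procedure was tested on simulated counts drawn from each comparison's means and library sizes, with 200 genes changed. In each of the 11 fits at least 98.5% of the genes changed by 2-fold and 100% of those changed by 4-fold were recovered. At most 13 unchanged genes per fit were falsely called. Of the genes changed by 1.5-fold, 89.1 to 100% were recovered. Smaller changes, such as the median rise of 1.31-fold with TCA in wt, were not simulated. Each simulation used a common dispersion (0.00147 to 0.00395), so genes and libraries with a larger spread were not tested. In camera, a list of random genes passed an unadjusted threshold of 0.05 for Cort against vehicle in wt and in tetra, but not in the other comparisons. Alternatives covered a mean of at least 50, no filter, centring of each library, no trend, a replicate block, a fold change of at least 2, a pseudocount of 5 for the differences, and leaving out each library in turn. Added after the values were seen were log2 of the normalised count plus 1 for the 6 comparisons, the deposited values for the differences, limma voom on the recovered counts, and a comparison of TCA plus Cort with Cort, which no deposited table holds. The planned tests made for counts were not run. The labels do not say whether replicates are separate cultures, so every p-value measures the spread between these samples only, which may be technical.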

Results

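RNA-seq of 24 libraries compared corticosterone (Cort), the main glucocorticoid of the mouse, with TCA and with their combination in C127 cells that carried GFP-tagged wild-type glucocorticoid receptor (wt) or the tetra form (tetra). Each line had 4 groups of 3 libraries: vehicle, and Cort, TCA and TCA plus Cort for 2 h. Between 22.02 M and 30.6 M exon reads were recovered per library, with 15794 to 16944 genes detected. The 45S ribosomal precursor Rn45s took 18.2 to 28.6% of these reads. Values are normalised read counts, mean ± SD with n = 3, and coordinates are those of mm10.

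Nr3c1 (chromosome 18, 39410545 to 39489776), which encodes the glucocorticoid receptor and is the gene replaced in these cells, was read in every library. In wt, vehicle libraries 1 to 3 held 4837, 5028 and 4722 reads, Cort libraries 5232, 5691 and 5804, TCA libraries 4329, 4125 and 4310, and TCA plus Cort libraries 4883, 3568 and 4763. In tetra, vehicle libraries held 5152, 5619 and 6625 reads, Cort libraries 4971, 4725 and 6576, TCA libraries 6739, 5426 and 4675, and TCA plus Cort libraries 6329, 5552 and 6003. These counts do not separate the transgene from the disrupted gene, so they check neither the knockout nor the receptor form. With TCA in wt the normalised count fell from 5159 ± 204.5 to 3985 ± 60.5 (adjusted p = 9.99e-06, n = 3). The other 5 comparisons gave no call for Nr3c1, with adjusted p between 0.388 in Cort against vehicle in wt and 0.984 in TCA plus Cort against TCA in wt.

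The first question was which genes Cort moves in wt cells. No group lacked a receptor form, so dependence on the receptor was not tested. Per1 (chromosome 11, 69098949 to 69109957), a clock gene and classic direct receptor target, rose from 392 ± 30.1 to 2681 ± 255 with Cort in wt (6.83-fold, adjusted p = 1.62e-16, n = 3). Tsc22d3 (chromosome X, 140539529 to 140548571), which encodes the anti-inflammatory protein GILZ, rose from 494 ± 30.5 to 1492 ± 112 (3.02-fold, adjusted p = 6.74e-13). Sgk1 (chromosome 10, 21994666 to 21999902), a kinase of ion transport, rose from 3438 ± 171 to 9189 ± 570.3 (2.67-fold, adjusted p = 3.57e-14). The growth-factor-like Ccn2 (chromosome 10, 24595442 to 24598682) rose from 45.5 ± 13.7 to 837 ± 31.8 (18.4-fold, adjusted p = 1.62e-16). Fkbp5 (chromosome 17, 28398753 to 28486149), whose protein restrains the receptor, rose 1.31-fold, from 1248 ± 12.3 to 1635 ± 46.9 (adjusted p = 7.97e-05).

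Other large rises with Cort in wt were those of Orm3 (3.94-fold), Tsku (2.29-fold), Ampd3 (1.83-fold), Lce1g (1.59-fold), Tob2 (1.57-fold) and Wee1 (1.499-fold). Orm3 has close paralogs in the acute-phase orosomucoid cluster, so its count is uncertain. Gm6093 rose from 4.09 ± 2.67 to 121 ± 3.74. Among circadian genes Per2 rose 1.52-fold, while the clock output genes Dbp and Nr1d1 were 1.45-fold and 1.35-fold lower. Vdr, the vitamin D receptor that also binds bile acids, rose 1.28-fold (adjusted p = 0.000743). Dusp1, at 218 ± 20.5 and 266 ± 19.9 (adjusted p = 0.194), and Klf9, at 553 ± 8.78 and 641 ± 22.2 (adjusted p = 0.121), were not called. In all, 304 of 12749 genes were called, 117 higher and 187 lower.

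Of 33 tested glucocorticoid-induced genes, 12 rose and 1 fell with Cort in wt, or 18 and 2 adjusted over the list alone. The list was called up (camera adjusted p = 5.21e-18, but adjusted p = 0.112 with an estimated correlation). The largest falls were in short noncoding RNAs. The RNase P RNA Rpph1 was 3.03-fold lower (adjusted p = 2.48e-11), the RNase MRP RNA Rmrp 3.24-fold, Rprl3 2.77-fold, Snora74a 4.02-fold, Scarna10 3.30-fold, Scarna6 4.95-fold and Mir1949 3.88-fold. Of 66 replication histone genes, whose near-identical copies make single counts uncertain, 35 fell (55 adjusted over the list alone; adjusted p = 2.06e-49, and adjusted p = 0.112 with an estimated correlation), with Hist4h4 1.49-fold and Hist2h4 1.47-fold lower. Of 77 ribosomal protein genes 27 fell (51 adjusted over the list alone; adjusted p = 2.06e-32, and adjusted p = 0.221 with an estimated correlation), among them Rpl41, 1.36-fold lower. Of 60 small nuclear and nucleolar RNAs 10 fell (17 adjusted over the list alone; adjusted p = 2.52e-06, and adjusted p = 0.275 with an estimated correlation). The histone, ribosomal protein and small RNA lists were chosen to stand for library composition, which could not be told apart from Cort here. The 21 transcripts of at most 400 nt that fell here had a median log2 ratio of -1.05 with Cort and of -0.85 with TCA against vehicle in wt.

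Plk2, a stress kinase, and Dusp4, a phosphatase of MAP kinases, were 1.49-fold and 1.42-fold lower with Cort in wt. Among 6 bile acid receptor genes 1 rose (2 adjusted over the list alone; adjusted p = 0.00491, and adjusted p = 0.228 with an estimated correlation). Among 19 mesenchymal markers only S100a4 fell, by either adjustment, 1.21-fold lower (list adjusted p = 0.0333, and adjusted p = 0.221 with an estimated correlation). Without vehicle library 3 the count of called genes was 148, 74 higher and 74 lower. Without Cort library 3 it was 499, 215 higher and 284 lower.

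In tetra, Per1 rose from 527 ± 14.1 to 2811 ± 208 with Cort (5.33-fold, adjusted p = 1.6e-14, n = 3), and Tsc22d3 rose from 558 ± 49.6 to 1881 ± 69.6 (3.37-fold, adjusted p = 2.22e-12). Fkbp5 rose from 1752 ± 53.02 to 3697 ± 76.7 (2.11-fold, adjusted p = 2.13e-11), and Dusp1, a phosphatase that dampens MAP kinase signalling, rose from 214 ± 8.61 to 588 ± 16.8 (2.75-fold, adjusted p = 3.46e-10). The acute-phase gene Orm3 (chromosome 4, 63356162 to 63359511) rose from 91.0 ± 4.34 to 2895 ± 387 (31.8-fold, adjusted p = 1.14e-15), with the same uncertainty about paralogs. Lcn2, which encodes the iron-binding protein lipocalin 2, rose from 0.998 ± 0.107, near the counting floor, to 58.3 ± 13.5 (adjusted p = 3.35e-08). In wt, Lcn2 had a mean of 0 without and 3.22 with Cort, below the filter.

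Sgk1 rose 1.98-fold with Cort in tetra, Klf9 1.73-fold, Spsb1 4.41-fold, Tsku 3.42-fold, Errfi1 3.30-fold, Sik1 2.55-fold, Tgm2 2.40-fold, Bcl2l1 2.30-fold, Ampd3 2.30-fold and Mknk2 1.98-fold. Errfi1 restrains EGF receptor signalling and Bcl2l1 protects against cell death. Among the falls, the EGF-responsive Phlda1 was 1.77-fold lower (adjusted p = 2.15e-07), the growth inhibitor Btg1 1.52-fold, Gas1 1.43-fold, the AP-1 gene Fosl1 1.42-fold, Aqp5 1.41-fold, Thbs1 1.40-fold, Midn 1.34-fold, Ajuba 1.33-fold and Cited2 1.32-fold. Of the 21 short transcripts that fell in wt, 5 were called lower in tetra, among them Rmrp (1.62-fold), Rprl3 (1.58-fold) and Rpph1 (1.54-fold). In all, 430 of 12863 genes were called, 318 higher and 112 lower. With wt, 73 rises and 36 falls were shared, where independent lists would share 2.87 and 1.65. Zbtb16 had a mean of at most 0.363 in any group of the 6 tables, and Mt2 had a mean of 0 in all of them.

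Of 34 glucocorticoid-induced genes, 25 rose and 2 fell with Cort in tetra, or 26 and 3 adjusted over the list alone (camera adjusted p = 5.57e-57, and adjusted p = 0.0151 with an estimated correlation). Of 16 circadian genes 4 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.00139, and adjusted p = 0.422 with an estimated correlation), with Per2 1.73-fold and Nfil3 1.71-fold higher and Nr1d1 1.31-fold lower. Of 19 genes of the receptor machinery 2 rose (3 adjusted over the list alone; adjusted p = 0.00714, and adjusted p = 0.422 with an estimated correlation): Fkbp5, and Nr3c2, which lost its call in 4 leave-outs, without a trend (adjusted p = 0.078) and on log2 normalised counts (adjusted p = 0.0721). Of 19 NRF2 targets 2 fell (3 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.478 with an estimated correlation): Hmox1 1.25-fold and Nqo1 1.37-fold lower. Hmox1 lost its call without Cort library 2 (adjusted p = 0.0644) or vehicle library 2 (adjusted p = 0.145), and Nqo1 in 4 leave-outs, in limma voom (adjusted p = 0.0591) and without a trend (adjusted p = 0.0584). Of 64 small nuclear and nucleolar RNAs 3 fell (9 adjusted over the list alone; adjusted p = 3.69e-07, and adjusted p = 0.422 with an estimated correlation). No ribosomal protein gene and no histone gene was called, also when adjusted over the list alone. Their lists as a whole were lower (adjusted p = 2.12e-18 and adjusted p = 0.036, but adjusted p = 0.444 and adjusted p = 0.774 with an estimated correlation).

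The difference between the wt and tetra lines was tested directly. Each receptor form came with its own line, so receptor form and line cannot be told apart. Fkbp5 rose less with Cort in wt than in tetra, by -0.69 ± 0.07 (SE) on the log2 scale (adjusted p = 6.59e-07, n = 3). So did Dusp1, by -1.17 ± 0.13 (adjusted p = 3.81e-06), Klf9, by -0.58 ± 0.09 (adjusted p = 0.000493), Orm3, by -2.99 ± 0.14 (adjusted p = 3.74e-12), and the interleukin 6 receptor gene Il6ra, by -1.48 ± 0.14 (adjusted p = 3.81e-07). Sgk1 rose more in wt, by 0.43 ± 0.07 (adjusted p = 0.000714), as did Ccn2, by 1.71 ± 0.24 (adjusted p = 0.000131). For Per1 (0.36 ± 0.10, adjusted p = 0.104), Tsc22d3 (-0.16 ± 0.10, adjusted p = 0.809) and Lcn2 (-2.80 ± 0.73, adjusted p = 0.0641) no difference was called. Other differences towards tetra were those of Nipal1 (-2.63), Errfi1 (-1.43), Slc25a33 (-1.36), Fam129a (-1.29) and Lims2 (-1.23), and towards wt those of Hes1 (0.90), Zfp697 (0.75) and Ddit4 (0.54). Fam129a and Ddit4 lost their calls without a trend (adjusted p = 0.0668 and adjusted p = 0.0608), and Fam129a also in 3 leave-outs and with no filter (adjusted p = 0.0719).

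In all, 144 of 12848 genes differed between wt and tetra in their response to Cort, 21 in favour of wt and 123 in favour of tetra. Without a trend the count was 88. Of 35 glucocorticoid-induced genes 2 differed towards wt and 14 towards tetra, or 3 and 20 adjusted over the list alone (adjusted p = 1.23e-24, and adjusted p = 0.00416 with an estimated correlation). Of 66 histone genes none differed (5 lower in wt adjusted over the list alone; list adjusted p = 2.31e-23, and adjusted p = 0.269 with an estimated correlation). Of 16 circadian genes none differed (1 towards wt and 4 towards tetra adjusted over the list alone; list adjusted p = 0.00851, and adjusted p = 0.218 with an estimated correlation). Of 20 genes of the receptor machinery 1 was lower in wt, also adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.504 with an estimated correlation).

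**Figure D1:**
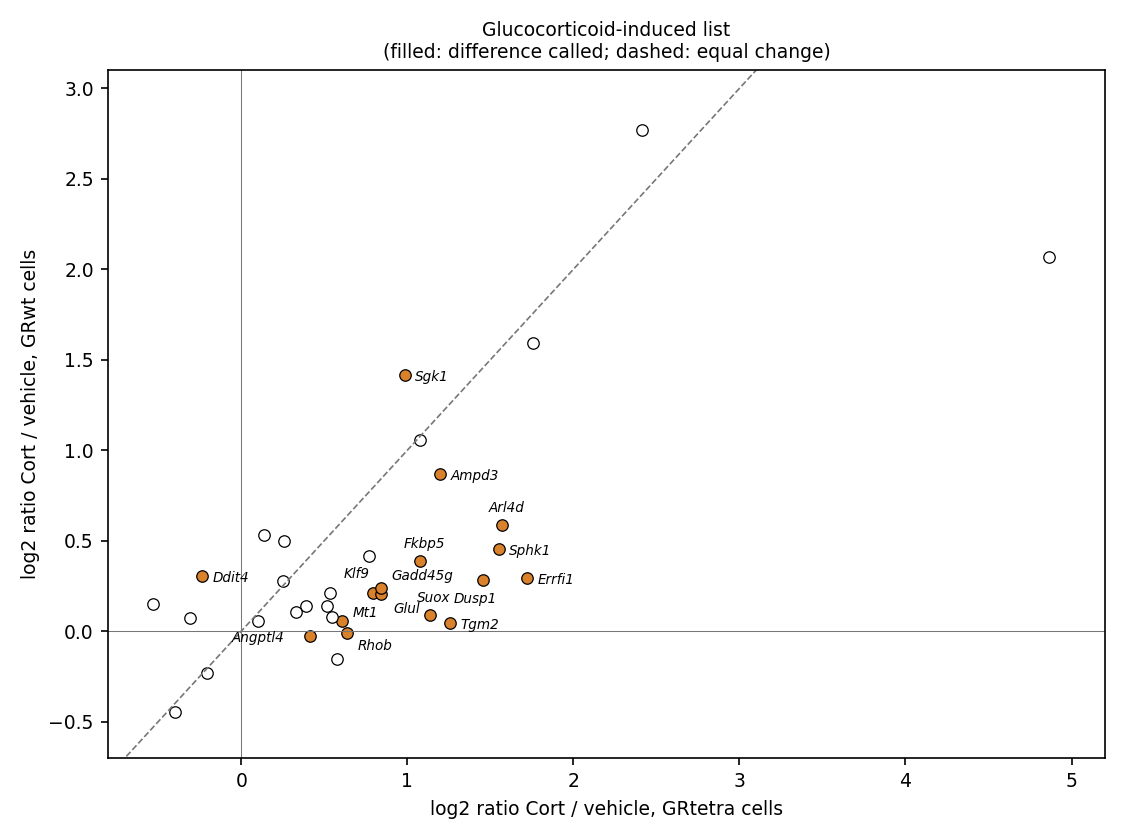
Each point is a gene of the glucocorticoid-induced list, with its log2 ratio of Cort over vehicle in tetra (x axis) and in wt (y axis), filled where the difference was called; the dashed line marks equal ratios. The 14 called genes below the line, such as Fkbp5 and Dusp1, have the higher ratio in tetra, and the 2 above it, Sgk1 and Ddit4, have the higher ratio in wt.

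The effect of TCA alone was asked next, which in wt cannot be told apart from a batch shared by the libraries with TCA. In wt, the pseudokinase gene Trib3 (chromosome 2, 152337425 to 152344060) rose from 1805 ± 146 to 7814 ± 191 (4.33-fold, adjusted p = 3.99e-12, n = 3). Chac1, which degrades glutathione, rose from 1145 ± 24.0 to 4068 ± 199.6 (3.55-fold, adjusted p = 6.97e-12). Ppp1r15a, which restores translation after stress, rose from 562 ± 39.1 to 2013 ± 212 (3.59-fold, adjusted p = 2.92e-10). Pparg (chromosome 6, 115422066 to 115490401), a lipid-sensing nuclear receptor, fell from 1735 ± 46.4 to 154 ± 12.4 (11.3-fold lower, adjusted p = 6.84e-13), and the lipid droplet gene Plin4 fell from 33462 ± 393 to 3839 ± 399 (8.72-fold lower, adjusted p = 6.84e-13). The tryptase gene Tpsab1 (chromosome 17, 25343245 to 25345562), a mast cell protease, fell from 35551 ± 2381 to 1079 ± 424 (33.0-fold lower, adjusted p = 2.49e-11).

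Further rises with TCA in wt were those of the cyclic AMP phosphodiesterase Pde4b (14.3-fold), Tenm4 (8.37-fold), Cp (5.94-fold), Cdsn (5.54-fold), Trim46 (4.84-fold), the growth arrest gene Gadd45a (4.78-fold), Arid5a (3.85-fold) and Nfil3 (3.504-fold). E230016M11Rik, 4.24-fold higher, overlaps Gadd45a and is uncertain. Further falls were those of Aldh3a1 (6.68-fold lower), Dusp4 (5.601-fold), Nqo1 (5.43-fold), Thbs1 (5.40-fold), Serpinb9e (5.40-fold) and the cyclooxygenase gene Ptgs1 (4.68-fold). Prl2c3, Prl2c4 and Prl2c2 were 20.7-fold, 20.4-fold and 19.9-fold lower, but these proliferin copies are nearly identical and share reads. Of the receptor targets, Fkbp5 rose 1.29-fold (adjusted p = 1.95e-05), Tsc22d3 1.27-fold (adjusted p = 0.00118) and Klf9 1.19-fold (adjusted p = 0.00428), Sgk1 was 1.54-fold lower (adjusted p = 1.21e-05), and Per1 (adjusted p = 0.349) and Dusp1 (adjusted p = 0.463) were not called. In all, 7303 of 12725 genes were called, 3670 higher and 3633 lower. No label names a batch, but a batch shared by the wt libraries with TCA could not be told apart from TCA. Had it begun with treatment, the fall of Tpsab1 needs a half-life of at most 23.8 min. Falls of at least 4-fold, in 86 genes, need at most 60 min. The median fold was 1.31 for the rises and 1.38 for the falls, and 772 genes changed by at least 2-fold.

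Of 24 genes of the unfolded protein response, 21 rose with TCA in wt, or 22 adjusted over the list alone (adjusted p = 2.51e-12, and adjusted p = 0.0215 with an estimated correlation), among them Asns at 2.13-fold. Of 23 cell cycle genes 20 rose (21 adjusted over the list alone; adjusted p = 3.01e-07, and adjusted p = 0.0328 with an estimated correlation), with Aurka 1.68-fold and Bub1 1.55-fold higher. Of 66 histone genes 63 rose and 1 fell, also adjusted over the list alone (adjusted p = 9.5e-18, and adjusted p = 0.423 with an estimated correlation), with Hist1h1a 2.64-fold higher. Of 19 NRF2 targets 3 rose and 15 fell, also adjusted over the list alone (adjusted p = 0.00478, and adjusted p = 0.557 with an estimated correlation): Gstm1 was 2.48-fold and Pgd 1.56-fold lower, while the cystine transporter Slc7a11 was 2.14-fold higher.

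Other lists moved both ways and were not called. Among all 12725 tested genes 57.39% were called, 3670 higher and 3633 lower. List counts near that share do not single out a list. Of 33 glucocorticoid-induced genes 16 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.625), with Ddit4 2.58-fold higher and Angptl4 1.99-fold and Tgm2 1.69-fold lower. Of 5 bile acid receptor genes 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.949, with a positive median and a negative test direction): Vdr was 1.44-fold and the bile acid receptor gene Nr1h4 1.63-fold lower, and the bile acid transporter gene Slc10a1 went from 17.0 ± 3.24 to 31.9 ± 8.39 (adjusted p = 0.0173, lost in 3 of 6 leave-outs). Of 18 mesenchymal markers 3 rose and 8 fell (the same adjusted over the list alone; adjusted p = 0.225), with Vim 1.75-fold and Pdgfrb 2.28-fold lower and Snai2 3.12-fold higher. Inflammatory genes had 5 rises and 5 falls among 16 (the same adjusted over the list alone; adjusted p = 0.949), and their median turned sign when scaled to total exon reads. Cholesterol synthesis (9 and 7 of 25, adjusted p = 0.949), p53 targets (5 and 6 of 16, adjusted p = 0.965), YAP targets (4 and 4 of 12, adjusted p = 0.949) and receptor machinery (7 and 7 of 19, adjusted p = 0.949) gave these counts also adjusted over the list alone. Heat shock genes had 9 rises and 3 falls among 15 (10 and 3 adjusted over the list alone; adjusted p = 0.145), with Hsp90aa1 1.65-fold higher. Too few markers of epithelial (1 rose and 1 fell of 3), immune (2 fell of 3) and endothelial cells (1 fell of 2) were expressed for a list test, and these counts were the same adjusted over the list alone.

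The nuclear RNA Malat1 made up 2.09 to 2.75% of exon reads in the 6 wt libraries without TCA, 0.661 to 0.905% in the 6 with TCA and 0.626 to 1.48% in tetra. In the authors' deposited table of this comparison, whose fold changes do not match the labelled groups, 0 genes had an adjusted p below 0.05 and 916 an unadjusted p below it.

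**Figure D2:**
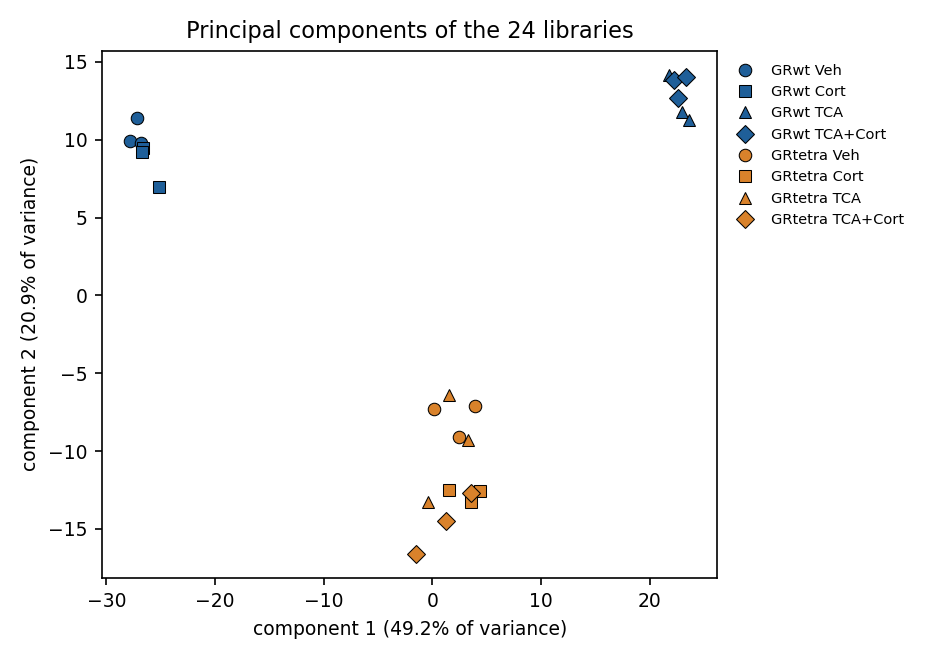
The 24 libraries are placed on principal components 1 (49.2% of variance, x axis) and 2 (20.9%, y axis). Each library is a point, with a colour per line and a marker shape per treatment. On component 1 the 6 wt libraries without TCA lie between -27.8 and -25.2, the 6 wt libraries with TCA between 21.8 and 23.7, and the 12 tetra libraries between -1.49 and 4.4.

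In tetra, TCA moved a few genes. Ccn1 (chromosome 3, 145646971 to 145649985), a matrix protein gene driven by YAP, rose from 3663 ± 238 to 8561 ± 1438 (2.34-fold, adjusted p = 4.22e-05, n = 3). Ankrd1, another YAP target, rose from 2466 ± 70.5 to 4543 ± 1067 (1.84-fold, adjusted p = 0.0186). Dusp1 went from 204 ± 8.21 to 304 ± 21.3 (adjusted p = 0.0813). Fkbp5 (1667 ± 52.7 and 1615 ± 19.8), Per1 (502 ± 13.7 and 565 ± 57.8) and Sgk1 (2866 ± 11.3 and 3514 ± 814) gave no call. Ccn1 and Ankrd1 were the only 2 calls among 13075 genes, with 524 at an unadjusted p below 0.05. The count was 6 without TCA library 1 or 3, 1 without TCA library 2 or vehicle library 1 or 2, 11 with a replicate block and 5 with no filter. Ankrd1 lost its call without TCA library 2 (adjusted p = 0.0901), vehicle library 1 (adjusted p = 0.202) or vehicle library 2 (adjusted p = 0.232). Ccn1 and Ankrd1 were both called lower with TCA in wt, where 6991 of the 12202 genes tested in both lines were called.

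Of 12 YAP targets in tetra with TCA 2 rose, or 5 adjusted over the list alone (adjusted p = 9.63e-13, and adjusted p = 0.328 with an estimated correlation). Of 24 immediate early genes 1 rose (4 adjusted over the list alone; adjusted p = 5.85e-10, and adjusted p = 0.118 with an estimated correlation), and Jun stood at 1.29-fold (adjusted p = 0.172). Of 16 inflammatory genes 0 were called (6 higher adjusted over the list alone; adjusted p = 2.49e-08, and adjusted p = 0.118 with an estimated correlation), and Ptgs2 stood at 1.35-fold (adjusted p = 0.941). Of 33 glucocorticoid-induced genes 0 were called (1 adjusted over the list alone; adjusted p = 0.175). The cholesterol synthesis, ribosomal protein and histone lists were lower as a whole (adjusted p = 0.000596, 6.97e-07 and 2.52e-10, each with adjusted p = 0.536 with an estimated correlation), with 0 members called, also adjusted over the list alone.

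Tested directly, the TCA effect differed between wt and tetra. For Tpsab1 it was lower in wt by -4.87 ± 0.26 (SE) on the log2 scale (adjusted p = 5.18e-11, n = 3), and for Pparg by -3.59 ± 0.12 (adjusted p = 2.48e-14). For Pde4b it was higher by 3.61 ± 0.30 (adjusted p = 1.26e-08) and for Tenm4 by 2.93 ± 0.17 (adjusted p = 9.33e-11). Sgk1 (-0.90 ± 0.16, adjusted p = 0.000115) and Nr3c1 (-0.47 ± 0.09, adjusted p = 0.000224) were lower and Fkbp5 (0.41 ± 0.07, adjusted p = 0.000138) higher in wt. Dusp1 differed by -0.46 ± 0.16 (adjusted p = 0.0292), a call lost in 5 leave-outs and on the deposited values (adjusted p = 0.0828). In all, 5140 of 12356 genes differed, 2508 towards a higher and 2632 towards a lower ratio in wt. A batch shared by the wt libraries with TCA would enter these differences too. Of 24 unfolded protein response genes 21 were higher, also adjusted over the list alone (adjusted p = 3.96e-14, and adjusted p = 0.0141 with an estimated correlation). Of 23 cell cycle genes 17 were higher (18 adjusted over the list alone; adjusted p = 2.76e-07, and adjusted p = 0.398 with an estimated correlation). Of 77 ribosomal protein genes 16 were higher (12 adjusted over the list alone; adjusted p = 0.00683, and adjusted p = 0.853 with an estimated correlation). Of 19 NRF2 targets 2 were higher and 9 lower, also adjusted over the list alone (adjusted p = 0.0277, and adjusted p = 0.494 with an estimated correlation). The histone list could not be tested here, because its symbols differ between the tables.

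The last question was whether Cort still acts when TCA is present. In wt, Per1 rose from 405 ± 30.0 to 2299 ± 123 with TCA plus Cort against TCA (5.68-fold, adjusted p = 9.89e-11, n = 3). Ccn2 rose from 97.0 ± 1.42 to 784 ± 90.7 (8.09-fold, adjusted p = 4.5e-09), Tsc22d3 from 695 ± 44.1 to 1471 ± 39.9 (2.12-fold, adjusted p = 4.32e-07) and Tsku from 1290 ± 46.8 to 2119 ± 21.8 (1.64-fold, adjusted p = 3.83e-06). Klf9, a repressor induced by glucocorticoids, rose 1.42-fold (adjusted p = 0.00434). Sgk1 rose from 2469 ± 332 to 3760 ± 252 (1.52-fold, adjusted p = 0.00558), a call lost without TCA plus Cort library 1 (adjusted p = 0.0784) or 2 (adjusted p = 0.103). Fkbp5, at 1780 ± 12.3 and 1885 ± 95.5 (adjusted p = 0.421), and Dusp1, at 263 ± 44.1 and 317 ± 35.8 (adjusted p = 0.272), were not called.

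Weaker rises in wt under TCA were those of Arrdc2 (1.65-fold), Zfp36l2 (1.496-fold), Sik1 (1.43-fold), Tns2 (1.35-fold) and Cebpb (1.28-fold). The prostaglandin synthase gene Ptgs2 was 1.30-fold lower (adjusted p = 0.0368), Inhba 1.37-fold, Adamts1 1.32-fold (adjusted p = 0.00558), Ankrd1 1.23-fold and Ahnak 1.22-fold. Each of these genes lost its call in at least 1 leave-out, and all but Arrdc2 and Tns2 also with a replicate block. In all, 53 of 12774 genes were called, 35 higher and 18 lower (28 and 22 with each library centred on its median, and 9 and 0 with a replicate block). The count was 12, 13 and 2570 without TCA library 1, 2 or 3, and 9, 6 and 13 without TCA plus Cort library 1, 2 or 3. Cort with and without TCA shared 19 rises and 2 falls in wt, where independent lists would share 0.322 and 0.268.

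Of 32 glucocorticoid-induced genes 10 rose in wt under TCA, or 16 with 1 fall adjusted over the list alone (adjusted p = 7.26e-16, and adjusted p = 0.161 with an estimated correlation). Of 23 cell cycle genes 0 were called (7 lower adjusted over the list alone; list adjusted p = 0.00321, and adjusted p = 0.161 with an estimated correlation), Ccna2 standing at 1.11-fold lower. Of 66 histone genes 1 rose (7 with 1 fall adjusted over the list alone; adjusted p = 0.00321, and adjusted p = 0.479 with an estimated correlation). Of 15 heat shock genes 0 were called (1 lower adjusted over the list alone; adjusted p = 0.0251, and adjusted p = 0.246 with an estimated correlation). Of 16 circadian genes Per1 alone was called (4 adjusted over the list alone; list adjusted p = 0.0458, and adjusted p = 0.405 with an estimated correlation). The circadian test and mean were positive but the median was near 0 and changed sign with the scaling.

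**Figure D3:**
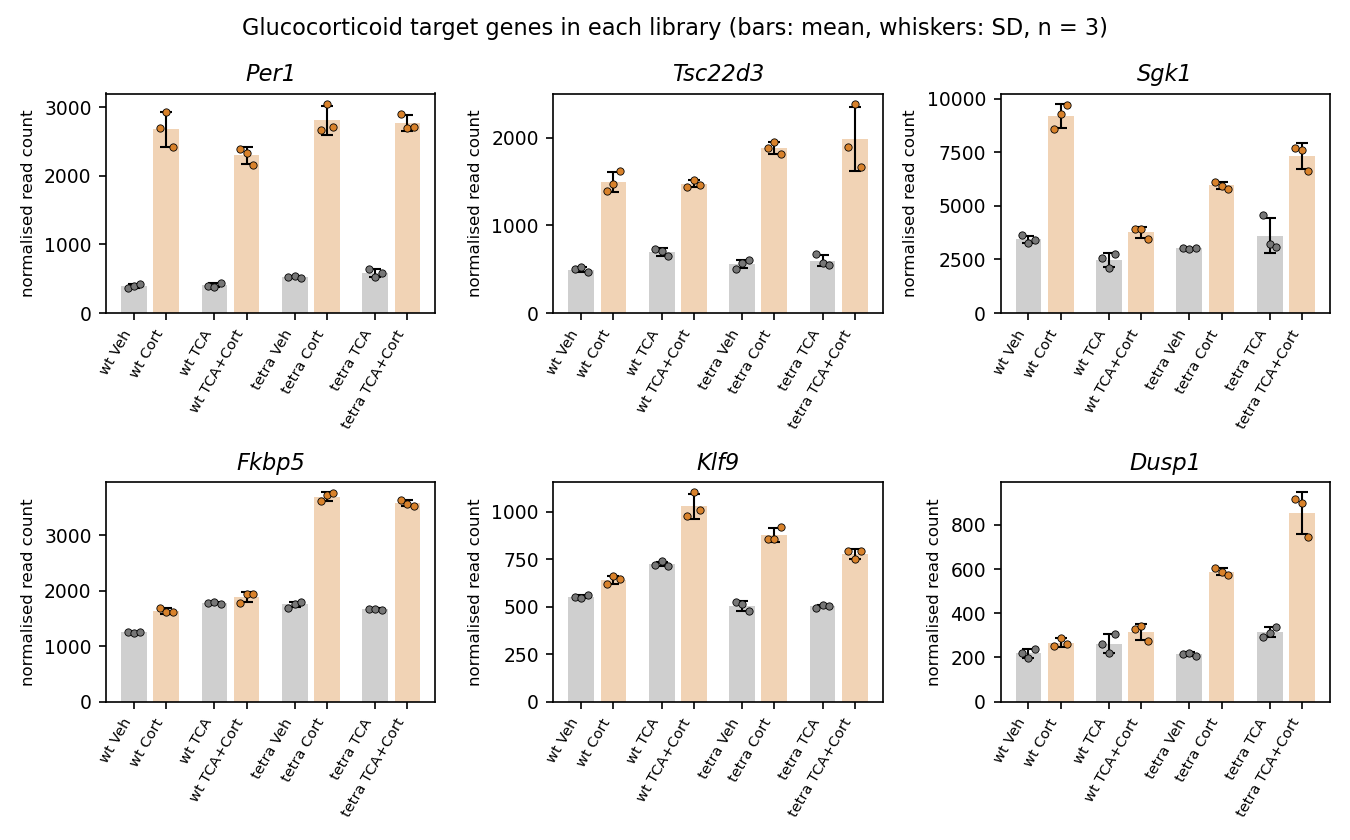
Normalised read counts of Per1, Tsc22d3, Sgk1, Fkbp5, Klf9 and Dusp1 (y axes) in the 3 libraries of each group (x axis), from the tables of Cort against vehicle and of TCA plus Cort against TCA in wt and tetra; bars are means, whiskers SD (n = 3) and points single libraries. Only changes within a table are compared, since each table was scaled on its own. The log2 ratio of Sgk1 with Cort was 1.42 without TCA and 0.61 under TCA in wt, and 0.98 and 1.035 in tetra.

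In tetra, Per1 rose from 582 ± 59.9 to 2772 ± 119.6 with Cort under TCA (4.76-fold, adjusted p = 4.87e-11, n = 3). Tsc22d3 rose from 598 ± 67.2 to 1982 ± 366 (3.31-fold, adjusted p = 1.16e-07), Fkbp5 from 1663 ± 16.2 to 3580.2 ± 57.9 (2.15-fold, adjusted p = 4.33e-08) and Dusp1 from 313 ± 22.6 to 854 ± 93.0 (2.73-fold, adjusted p = 1.37e-07). Sgk1 rose from 3618 ± 835 to 7310 ± 607 (2.02-fold, adjusted p = 5.07e-05). Orm3 rose 34.2-fold, from 86.3 ± 8.15 to 2953 ± 361 (adjusted p = 4.07e-14), and Lcn2 from 1.75 ± 1.06 to 71.1 ± 12.9 (adjusted p = 2.5e-07).

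Spsb1 (5.17-fold), Arl4d (3.91-fold), Errfi1 (3.66-fold), Tsku (3.62-fold), Adgra1 (3.36-fold), Sik1 (2.67-fold), Tgm2 (2.61-fold), Bcl2l1 (2.35-fold) and Klf9 (1.55-fold) also rose. Phlda1 was 1.70-fold lower (adjusted p = 6.95e-05), the plasminogen activator gene Plau 1.68-fold, Btg1 1.57-fold, the neurotrophin gene Bdnf 1.56-fold, Mylip 1.45-fold, Cited2 1.37-fold, Dipk2a 1.37-fold and Irs1, an insulin signalling adaptor gene, 1.34-fold. Ankrd1 was 1.47-fold lower (adjusted p = 0.0427), lost in 4 leave-outs and without a trend (adjusted p = 0.0646). Irs1, Mylip and Plk2 (1.33-fold lower) each lost their call in 2 leave-outs. In all, 219 of 12830 genes were called, 182 higher and 37 lower. With Cort alone in tetra, 173 rises and 29 falls were shared, where independent lists would share 4.52 and 0.325.

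Of 35 glucocorticoid-induced genes 24 rose and 1 fell in tetra under TCA, or 28 and 2 adjusted over the list alone (adjusted p = 1.88e-60, and adjusted p = 0.0313 with an estimated correlation). Of 16 p53 targets 2 rose (4 adjusted over the list alone; adjusted p = 0.000253, and adjusted p = 0.58 with an estimated correlation), Btg2 1.495-fold and the cell cycle inhibitor gene Cdkn1a 1.52-fold. Of 16 circadian genes 3 rose (4 adjusted over the list alone; adjusted p = 0.00253, and adjusted p = 0.351 with an estimated correlation). The other list calls held no called gene, also adjusted over the list alone: cholesterol synthesis and small RNAs lower (adjusted p = 0.00117 and adjusted p = 0.0235), and ribosomal protein, histone and heat shock genes higher (adjusted p = 0.00252, 0.00665 and 0.028). With an estimated correlation the heat shock list had adjusted p = 0.58 and the other 4 had adjusted p = 0.785 with an estimated correlation.

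Under TCA the wt and tetra lines differed again, with receptor form and line still not told apart. Fkbp5 rose less in wt than in tetra by -1.02 ± 0.08 (SE, log2; adjusted p = 2.93e-07, n = 3), Dusp1 by -1.17 ± 0.17 (adjusted p = 0.00075), Orm3 by -3.80 ± 0.19 (adjusted p = 9.44e-10) and Spsb1 by -2.24 ± 0.20 (adjusted p = 2.66e-06). Nipal1 (-2.26), the vasodilator peptide gene Adm (-1.74), Errfi1 (-1.71), Il6ra (-1.66), Arl4d (-1.66) and Map7d2 (-1.55) followed. Sgk1 (-0.42 ± 0.17, adjusted p = 0.542), Tsc22d3 (-0.64 ± 0.15, adjusted p = 0.0532) and Per1 (0.25 ± 0.11, adjusted p = 0.596) were not called. Lcn2 differed by -3.87 ± 0.80 (adjusted p = 0.0278), a call lost in 9 leave-outs and without a trend (adjusted p = 0.0519). In all, 84 of 12809 genes differed, 15 towards wt and 69 towards tetra, with 54 and 53 without wt TCA plus Cort library 2 or 3. Of 34 glucocorticoid-induced genes 1 differed towards wt and 12 towards tetra, or 4 and 22 adjusted over the list alone (adjusted p = 3.37e-27, and adjusted p = 0.0135 with an estimated correlation).

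Among the other lists under TCA, heat shock genes were lower in wt as a whole (adjusted p = 0.000416, and adjusted p = 0.201 with an estimated correlation), with 0 members called, also adjusted over the list alone. Of 18 genes of the receptor machinery 1 was lower in wt, also adjusted over the list alone (adjusted p = 0.0243, and adjusted p = 0.846 with an estimated correlation). Cell cycle genes were lower (adjusted p = 0.015) and cholesterol synthesis genes higher (adjusted p = 0.0334), each with adjusted p = 0.846 with an estimated correlation and with 0 members called, also adjusted over the list alone. Of 16 p53 targets 0 were called (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.0336, and adjusted p = 0.846 with an estimated correlation).

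Whether TCA altered the Cort response was tested within each line. In wt, a Cort response that differs between batches could not be told apart from an action of TCA. In wt, the Cort response of Sgk1 was smaller with TCA by -0.80 ± 0.11 (SE, log2; adjusted p = 0.000526, n = 3). That of Tsc22d3 was smaller by -0.51 ± 0.09 (adjusted p = 0.00489), of Ccn2 by -1.22 ± 0.22 (adjusted p = 0.00426), and of Fkbp5 by -0.31 ± 0.07 (adjusted p = 0.016). The calls of Tsc22d3, Ccn2 and Fkbp5 were lost without a trend (adjusted p = 0.0676, 0.0822 and 0.0789). On the deposited values those of Ccn2 (adjusted p = 0.269) and Tsc22d3 (adjusted p = 0.0524) were lost, and that of Fkbp5 with a replicate block (adjusted p = 0.0906) and without TCA plus Cort library 1 (adjusted p = 0.0683). The collagen-binding integrin gene Itga10 (-1.31, adjusted p = 0.0518 with a replicate block) and Spsb1 (-0.86, adjusted p = 0.0813 without a trend and adjusted p = 0.0502 with the block) also responded less. Igip (-1.01, adjusted p = 0.0638 without a trend) had a log2 ratio of 0.60 with Cort alone and of -0.41 under TCA, and Kbtbd8 (-0.85) of 0.45 and -0.40. Per1 (-0.26 ± 0.11, adjusted p = 0.163), Klf9 (0.29 ± 0.08, adjusted p = 0.0592) and Dusp1 (-0.01 ± 0.17, adjusted p = 0.987) gave no call.

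The positive differences in wt were led by short RNAs: Scarna10 (1.89), Rpph1 (1.65), Rprl3 (1.58) and Rmrp (1.26), which were lower with Cort alone. Rprl3 (adjusted p = 0.0503) and Rmrp (adjusted p = 0.0904) lost their calls without a trend. In all, 449 of 12801 genes differed, 235 positive and 214 negative (209 and 326 with each library centred on its median). The count was 225, 242 and 1637 without TCA library 1, 2 or 3, 153 and 145 without TCA plus Cort library 1 or 2, 160 without vehicle library 3, and 46 without a trend. Of 33 glucocorticoid-induced genes 2 were positive and 4 negative, or 5 and 5 adjusted over the list alone (adjusted p = 0.467). Of 66 histone genes 25 were positive (42 adjusted over the list alone; adjusted p = 2.6e-26, and adjusted p = 0.221 with an estimated correlation), and of 77 ribosomal protein genes 21 (32 adjusted over the list alone; adjusted p = 1.63e-16, and adjusted p = 0.632 with an estimated correlation).

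In tetra no gene was called for this difference: limma gave 0 of 12846, with 514 at an unadjusted p below 0.05, and limma voom also gave 0. Fkbp5 differed by 0.03 ± 0.07 (SE, log2), Per1 by -0.16 ± 0.11, Sgk1 by 0.05 ± 0.15, Dusp1 by -0.01 ± 0.12 and Lcn2 by -0.10 ± 0.50. The ribosomal protein list was higher under TCA as a whole (adjusted p = 1.42e-24), as were the histone list (adjusted p = 8.32e-05), p53 targets (adjusted p = 0.00234) and NRF2 targets (adjusted p = 0.0389), while the cholesterol synthesis list was lower (adjusted p = 0.0187), each with adjusted p = 0.73 with an estimated correlation and 0 members called, also adjusted over the list alone.

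The authors' deposited tables call 270 genes for Cort in wt, 245 for TCA plus Cort against TCA in wt, 9 for TCA in tetra, 405 for Cort in tetra and 249 for TCA plus Cort against TCA in tetra at an adjusted p below 0.05. Of the 245, 75 were higher and 170 lower, the opposite balance to the 35 higher and 18 lower called by limma.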

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

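The tests of a mixture, of a shared batch and of the short RNAs, the counts of other splits of the samples, limma voom and the deposited values for the differences were chosen only after the results were seen. The results here were singled out because the same contrast, tested directly with limma, differed between the wt and tetra lines or between cells with and without TCA. Differences are on the log2 scale. Splits of the libraries within each table also break up the treatment effects that a difference is made of, so their counts do not settle whether chance gave a difference.

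For the TCA effect in wt minus that in tetra, 5140 genes were called. The positive differences were Car6 4.32, Pde4b 3.61, Tenm4 2.93, Itgb7 2.91, Fyb2 2.64, Cdsn 2.39, Trim46 2.30 and Soat2 2.26. The negative ones were Tpsab1 -4.87, Prl2c2 -4.25, Megf10 -4.21, Prl2c3 -4.20, Prl2c4 -4.19, Pparg -3.59, Hsd17b14 -3.41 and Serpinb1a -3.41. Of the fixed panel, Fkbp5 differed by 0.41, Nr3c1 by -0.47, Sgk1 by -0.90 and Dusp1 by -0.46, the last not called in 5 of the 12 fits without a library. Of 100 splits of the 12 libraries, 5 called as many genes, the real split included, with 5656 in the highest other. All 5 kept the wt vehicle and wt TCA libraries whole, and since TCA called 2 genes in tetra, splitting the tetra libraries alone leaves the count much as it was.

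For the Cort effect in wt minus that in tetra, 144 genes were called. The positive differences were Ccn2 1.71, Hes1 0.90, Cd300lb 0.78, Neat1 0.76, Zfp697 0.75, 9030025P20Rik 0.63, Mir100hg 0.61 and Ddit4 0.54. The negative ones were Orm3 -2.99, Nipal1 -2.63, Notch4 -1.53, Il6ra -1.48, Errfi1 -1.43, Slc25a33 -1.36, Fam129a -1.29 and Lims2 -1.23. Of the panel, Sgk1 differed by 0.43, Fkbp5 by -0.69, Dusp1 by -1.17 and Klf9 by -0.58. Of 100 splits, 5 called as many genes, the real split included, with 194 in the highest other and the tetra groups whole in all 5. Without a trend 88 genes were called, and Ddit4, Mir100hg, Fam129a, Neat1, Notch4 and Cd300lb were not among them. Of the 12 fits without a library, 9 did not call Notch4, 7 Neat1, 7 9030025P20Rik, 6 Cd300lb and 3 Fam129a. 9030025P20Rik and Cd300lb were also lost with a replicate block (adjusted p = 0.0508 and 0.0521), and both, Fam129a, Neat1 and Notch4 with no filter (adjusted p = 0.0505 to 0.127). Cd300lb was lost in limma voom (adjusted p = 0.207) and on the deposited values (adjusted p = 0.432) too.

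For the Cort effect under TCA in wt minus that in tetra, 84 genes were called. The positive differences were Syn1 1.32, Shfl 1.05, Adamts6 0.84, Ahr 0.67, Gas1 0.64, Ier3 0.61, Mylip 0.60 and Artn 0.59. The negative ones were Orm3 -3.80, Nipal1 -2.26, Spsb1 -2.24, Adm -1.74, Errfi1 -1.71, Il6ra -1.66, Arl4d -1.66 and Map7d2 -1.55. Of the panel, Fkbp5 differed by -1.02, Dusp1 by -1.17 and Lcn2 by -3.87. Of 100 splits, 12 called as many genes, with 253 in the highest other. Without wt TCA plus Cort replicates 2 and 3 in turn, 54 and 53 genes were called. Of the fits without a library, 5 to 10 did not call Syn1, Shfl, Ahr, Gas1, Ier3, Mylip, Artn or Lcn2. Without a trend Ahr, Gas1, Ier3, Mylip and Lcn2 were lost (adjusted p = 0.0519 to 0.176), with a replicate block Ahr, Artn, Gas1, Ier3, Mylip and Shfl (adjusted p = 0.0551 to 0.0961), with no filter Ahr, Artn, Ier3, Shfl and Syn1 (adjusted p = 0.0502 to 0.0819), and in limma voom Shfl (adjusted p = 0.0523).

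For the Cort effect under TCA minus the Cort effect alone in wt, 449 genes were called. A batch shared by the wt libraries with TCA cannot be told apart from TCA here either. The positive differences were Scarna10 1.89, Scarna6 1.84, Mir1949 1.71, Rpph1 1.65, Rprl3 1.58, Snora74a 1.37, Rmrp 1.26 and Frat2 1.06. The negative ones were Itga10 -1.31, Ccn2 -1.22, Igip -1.01, Prl2c4 -0.95, Prl2c3 -0.93, Spsb1 -0.86, Kbtbd8 -0.85 and Sgk1 -0.80, and of the panel also Tsc22d3 -0.51 and Fkbp5 -0.31. Of 100 splits, 2 called as many genes, with 764 in the highest other. That other split kept the vehicle and Cort libraries whole and set TCA replicates 1 and 2 beside TCA plus Cort replicate 3. The count itself rests on single libraries: without TCA replicates 1, 2 and 3 it was 225, 242 and 1637, without TCA plus Cort replicates 1 and 2 it was 153 and 145, and without vehicle replicate 3 it was 160. It was 46 without a trend and 92 with a replicate block. Snora74a, Frat2, Prl2c3, Prl2c4 and Scarna6 lost the call in 3 to 8 of the 12 fits without a library, with no filter, without a trend and with the block, and Fkbp5 lost it in 1 such fit, without a trend and with the block. Without a trend Ccn2, Igip, Mir1949, Rmrp, Rprl3, Spsb1 and Tsc22d3 were lost too, and with the block Itga10 and Spsb1. On the deposited values Ccn2 (adjusted p = 0.269), Tsc22d3 (adjusted p = 0.0524), Prl2c3 and Prl2c4 were lost, and in limma voom Snora74a, Prl2c3 and Prl2c4.

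The broad TCA difference in wt was weighed first. It could be technical, or an effect of TCA through the wild-type receptor, or a difference between the cultures. After each library's trend on GC content and log2 length was removed, 7758 genes were called, against 7266 before on the same 12622 genes, with 6860 in both. This argues against such a bias as the whole cause. Tetra cells mixed into the wt TCA libraries would place genes between the wt and the tetra vehicle levels. Of the 772 genes changed by at least 2-fold, 402 (52.07%) lay beyond the tetra vehicle level by more than 1.5-fold, just above the bound of 50% set for this test, which replaced an earlier version that no gene could enter. That argues against a mixture as the whole cause only. In wt the fall of Tpsab1, had it begun with treatment, needs a half-life of at most 23.8 min, and 86 genes fell by at least 4-fold, which needs at most 60 min. No label names a culture or library batch, but a batch shared by the 6 wt libraries with TCA would coincide with TCA in both comparisons. The TCA effect under Cort correlated with that without Cort at r = 0.8818 across genes, which are not independent replicates, and since either a batch or a real effect would give this, it decides nothing. Batch and TCA cannot be told apart here, because every wt library with TCA would share the batch, and the biological difference between the receptor forms was not tested apart from it.

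The lower short RNAs with Cort in wt were weighed next, over the 21 transcripts of at most 400 nt that fell. Their median log2 ratio was -1.05 with Cort and -0.85 with TCA against the same vehicle libraries. A higher yield of short RNAs in the 3 wt vehicle libraries would give both, but the RNAs were picked for falling against these libraries, so the value with TCA is partly built in and that explanation stays open. In TCA plus Cort against TCA in wt the median of these RNAs was -0.0635 (interquartile range over the RNAs 0.35), with 0 called lower. Single RNAs lay between -0.772 (Rnu3a) and 0.257 (Mir5121). This argues against a lowering by Cort of the same size with TCA, for the set as a whole only. The libraries compared carry a structure that the labels do not explain, so a smaller lowering stays open. In tetra the medians were -0.58 with Cort, -0.17 with TCA and 0.07 in TCA plus Cort against TCA. An action of Cort on these RNAs only without TCA stays open too.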

How the results depend on the processing

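The deposited values for differences, log2 normalised counts for the comparisons, limma voom and the comparisons of TCA plus Cort with Cort were chosen after the data were seen. In 6880 alternatives to 442 gene results, 6226 kept direction and side of the threshold, 538 lost a call, 86 gained a call and 30 changed direction. Of 319 called gene results, 192 lost the call under some alternative and 0 changed sign; 11 uncalled ones changed sign.

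A fold change of at least 2 left 772, 27 and 7 genes for TCA, Cort and TCA plus Cort against TCA in wt, 1, 54 and 47 in tetra, and 720, 24, 23 and 18 for the differences of TCA, of Cort, of Cort under TCA between wt and tetra and of Cort with and without TCA in wt. It left 762 and 1 for TCA plus Cort against Cort in wt and tetra, by construction. Shared calls with that fold numbered 11 (TCA and Cort in wt), 0 (TCA, and TCA plus Cort against TCA, in wt), 6 (Cort with and without TCA in wt), 40 (the same in tetra), 10 (Cort in wt and tetra) and 6 (Cort under TCA in wt and tetra). The replicate block gave 9 for TCA plus Cort against TCA in wt, 11 for TCA in tetra, 92 for Cort with and without TCA in wt and 77 for TCA plus Cort against Cort in tetra. Centring turned 235 higher and 214 lower genes for Cort with and without TCA in wt into 209 and 326, and 35 and 18 for TCA plus Cort against TCA in wt into 28 and 22. No filter gave 5 for TCA in tetra and 281 for Cort with and without TCA in wt. No trend gave 88 for Cort in wt minus tetra, 46 for Cort with and without TCA in wt and 0 for TCA plus Cort against Cort in tetra, where 8 were called with a trend. Except where fold or numbers of samples are the construction, the cause was not tested. An estimated correlation left 2, 0 and 0 of 4, 6 and 5 lists in wt, 0, 1 and 1 of 6, 7 and 8 in tetra, and 1, 1, 1, 0 and 0 of 4, 4, 6, 2 and 5 for the differences. The block called 7 lists instead of 5 for TCA plus Cort against TCA in wt. Replicate numbers showed no clear pairing of the samples: of 18 pairs, 5 correlated above 0.1 (range -0.43 to 0.49), and 4 matched their own number best. With 3 libraries per group this does not exclude a pairing. The block gave more calls in some comparisons, such as 614 against 430 for Cort in tetra, and fewer in others, such as 249 against 304 for Cort in wt.

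Leaving out a library gave 6434 to 7586 calls for TCA, 148 (without vehicle 3) to 499 (without Cort 3) for Cort and 6 to 2570 for TCA plus Cort against TCA in wt: 12, 13 and 2570 without TCA 1, 2 and 3, and 9, 6 and 13 without TCA plus Cort 1, 2 and 3. In tetra it gave 1 (without vehicle 1, vehicle 2 or TCA 2) to 6 (without TCA 1 or 3), 309 to 427 and 146 to 282. For the differences it gave 4405 to 5171, 115 to 158, 53 (without wt TCA plus Cort 3; 54 without 2) to 119, and 0 in tetra. For Cort with and without TCA in wt it gave 145 to 1637: 225, 242 and 1637 without TCA 1, 2 and 3, 153 and 145 without TCA plus Cort 1 and 2, and 160 without vehicle 3. For TCA plus Cort against Cort it gave 6715 to 7795 in wt and 1 to 270 in tetra: 1, 3 and 270 without TCA plus Cort 1, 2 and 3, and 3, 1 and 3 without Cort 1, 2 and 3. An arm of 2 libraries is assumed to vary like the other groups.

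These uncalled log2 values changed direction, and the cause was not tested. Dusp1 with TCA in wt went from 0.0745 to -0.0066 without TCA 3 (highest 0.1569). Nr3c1 with TCA plus Cort against TCA in wt was -0.0039 when centred, and -0.007, -2e-04 and -0.0078 without TCA 2, TCA 3 and TCA plus Cort 3 (highest 0.0137). Klf9 with TCA in tetra was -0.01 without vehicle 3 (highest 0.034). On the deposited values Per1 in Cort under TCA, wt minus tetra, was -0.0831. Dusp1 in Cort with and without TCA in wt was 0.0183 on deposited values and 0.1099, 0.0866, 0.0622 and 0.051 without TCA 3, TCA plus Cort 3, vehicle 2 and Cort 2 (lowest -0.1336). For the same difference in tetra the deposited values gave Tsc22d3 0.1921, Per1 0.1578, Dusp1 0.275 and Lcn2 0.2391, and a pseudocount of 5 gave Lcn2 0.115. Leave-outs there gave Nr3c1 0.0189 (TCA 1; lowest -0.1183), Tsc22d3 0.0515, 0.0789 and 0.0333 (TCA 1, TCA plus Cort 3, vehicle 1; lowest -0.1793), Sgk1 -0.0247 and -0.054 (TCA 2, TCA 3; highest 0.2336), Dusp1 0.042, 0.0828, 0.0225 and 0.0114 (TCA 3, TCA plus Cort 3, vehicle 3, Cort 1; lowest -0.065), and Lcn2 0.1927, 0.0363 and 0.0098 (TCA 1, TCA plus Cort 3, Cort 2; lowest -0.3096).

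The planned tests made for counts were not run, and limma voom on the recovered counts was added instead. A pseudocount of 5 was not run for the 6 comparisons. Genes near 3 counts, such as Lcn2 in wt, are limited by depth.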

Other observations

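The comparisons of TCA plus Cort with Cort and their alternatives, the distances between group means, the search over groupings of the authors' table and the counts of other splits were chosen only after the results were seen.

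The tables allow a further comparison, TCA plus Cort against Cort, which no deposited table holds. Its genes were chosen after their values were seen. In wt, limma called 7557 of 12858 genes, 3828 higher and 3729 lower, with 8070 at an unadjusted p below 0.05. Tenm4 was 9.33-fold higher, Trib3 4.52-fold higher, Pparg 9.34-fold lower and Tpsab1 35.8-fold lower. Of the calls, 5698 were shared in direction with TCA against vehicle, where independent lists would share 2161, and 49 went the opposite way. A batch shared by the wt libraries with TCA would give such sharing too, so it does not tell TCA from a batch. In tetra, 8 of 12869 genes were called, all higher, among them Ccn1 from 4354 ± 25.7 to 9666 ± 1450 (2.22-fold, adjusted p = 2.58e-05, n = 3), Ankrd1 (1.66-fold), Trib1 (1.62-fold), Ccn2 (1.51-fold), Dusp1 (1.48-fold), Ptgs2 (1.45-fold) and Errfi1 (1.36-fold). With each library centred the split was 9 higher and 2 lower, and without a trend 0 genes were called. The count was 1, 3 and 270 without tetra TCA plus Cort replicates 1, 2 and 3, and 3, 1 and 3 without tetra Cort replicates 1, 2 and 3. Unadjusted, 845 tetra genes passed 0.05, and the correlation with TCA against vehicle across genes was 0.101.

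Comparisons against shared vehicle libraries share their chance values. TCA and Cort in wt shared 41 rises and 90 falls, where independent lists would share 32.7 and 53.9, and 96 calls went opposite ways, where such lists would give 86.5. Their fold changes correlated at r = 0.235 across genes with a covariance of 0.0244, and 50 simulations of unchanged groups against the same controls gave 0.497 and 0.0103. Part of the excess may come from the shared controls, since 3 vehicle libraries cannot be divided into parts of at least 2, and leaving out wt vehicle replicate 3 gave 148 Cort calls.

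Among group means, 457 of 11127 genes lay more than 2-fold apart between vehicle and TCA in wt, 195 between the wt and tetra vehicle groups, 138 between TCA in wt and vehicle in tetra, 19 between vehicle and Cort in wt, 6 between TCA with and without Cort in wt, and 1 between vehicle and TCA in tetra.

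The authors' deposited table of TCA in wt calls 0 genes, with 916 at an unadjusted p below 0.05. Over 230 groupings of its 6 libraries, vehicle libraries 1 and 2 against vehicle library 3 with TCA libraries 1 and 2 gave back the deposited log2 fold changes with a median absolute difference of 0.000638, against 0.102 for the labelled groups. On that grouping limma called 0 genes, with 777 at an unadjusted p below 0.05. The command in that table's header names 5 groups for 6 library columns. A candidate explanation for the absence of calls in that table is a shift of the group names by a column. In the other 5 tables the labelled grouping gave the smallest difference. The header commands of 5 tables name Halo where the columns name GFP.

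For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real splits called 7303 genes for TCA in wt (highest other 0), 304 for Cort in wt (1), 53 for TCA plus Cort against TCA in wt (312, in a split with TCA libraries 1 and 2 beside TCA plus Cort library 3), 2 for TCA in tetra (2), 430 for Cort in tetra (1), 219 for TCA plus Cort against TCA in tetra (82), 7557 for TCA plus Cort against Cort in wt (0) and 8 for the same in tetra (3). The split with 312 calls exceeds the real count several times, so those libraries carry a structure that the labels do not explain. Rn45s took 27.9% of exon reads in TCA library 3 and 27.7 and 28.6% in TCA plus Cort libraries 1 and 2, against 23.9 and 21.3% in TCA libraries 1 and 2 and 25.6% in TCA plus Cort library 3. Without TCA replicate 3 the real count was 2570, and without any other library of these 6 it was 6 to 13. Splits that called as many genes as the real one, itself included, numbered 2 for TCA plus Cort against TCA in wt and for TCA in tetra and 1 for the other 6. For the Cort effect under TCA minus the Cort effect alone in tetra, with 0 calls and 514 genes at an unadjusted p below 0.05, all 100 splits called as many, with 54 in the highest other.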
